A study of Mus musculus with 8 samples.

How the data were processed

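RNA was measured by bulk sequencing in 8 libraries of mouse T-cell progenitors that had been grown from bone marrow. The libraries fall into 4 groups of 2, crossed by sort gate and by guide RNA. CRISPR guides were delivered by retrovirus, with control guides or with 3 guides against Stat5a and 3 against Stat5b. Cells then grew for 6 days on OP9-DLL1, a bone-marrow stromal line that displays a Notch ligand, with IL-7 and Flt3 ligand at 10 ng/ml each. Groups and replicate numbers come from the labels alone. What the control guides target is not given in the sources used here.

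The submitters' processing notes name bcl2fastq 1.8.4, STAR 2.4.0 and RSEM 1.2.25 and the GRCm38/mm10 genome. Per the file headers, HOMER's analyzeRepeats then gave the authors' deposited counts, raw tags over the exons of 1 RefSeq transcript per gene, without adjustment. A companion table holds deposited FPKM values, made by the authors with the same program per kilobase of transcript and scaled to the tags of the whole library. The library kit keeps no strand, and the headers name no strand option, so a count can include reads of a gene that overlaps on the other strand. All 24506 symbols of the count table carry whole numbers. Compared with the counts, 3271 symbols of the FPKM values have another representative transcript, 394 genes lie at more than 1 locus, and 44 tested genes have counts identical to those of another gene. Coordinates are mm10 and count from 1.

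Total counts per library ran from 22146490 to 31209177. The FPKM denominators were larger, so that 70.3 to 74.1% of tags fell in the count table. The 10 most abundant genes took 4.14 to 4.73% of counts, and the ribosomal precursor Rn45s took 0.318 to 0.852%. Between replicates the chi-square per degree of freedom across genes ran from 23.7 to 64.5, so the spread between libraries was far above counting error.

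Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr, which left 13775, and libraries were scaled by TMM. A quasi-likelihood F-test, two-sided, was fitted to all 8 libraries with 1 mean per group, and p-values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. The 5 comparisons were sgStat5 against control in each gate, the difference between these effects, and the late against the early gate within each guide arm. SE stands for the standard error of the log2 fold change. For edgeR it was derived as the absolute log2 fold change divided by the square root of the F statistic. The labels do not say whether replicates are separate cultures or animals, and Xist and Y-linked genes differ between the replicate numbers in every group, so the numbers do not stand for repeats of 1 pool of cells. All p-values measure only the spread between these samples. The tests, the gene lists, the comparisons, the named-gene rule and the first set of alternatives were fixed before the data were examined.

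Replicate numbers recur in every group, so whether they pair the libraries was checked. Deviations of replicate 1 from its group mean correlated between groups across genes, with 6 coefficients from 0.421 to 0.578. The first component of a principal component analysis held 32.7% of variance, and the second, which held 31.1%, separated the replicate numbers. The replicate number was therefore also fitted as a block, and blocked values stand beside the others. The common dispersion was 0.0853 without the block and 0.0178 with it. Residual degrees of freedom were 4 and 3.

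The design was tested on simulated data with 13775 genes, of which 100 had a 2-fold and 100 a 4-fold change. Without the block, edgeR recovered 32% of 2-fold and 66% of 4-fold changes before commitment, 31% and 66% after commitment, and 4% and 47% for the difference between these effects. It recovered 31% and 71% for the stage difference in control cells and 31% and 64% in sgStat5 cells. With the block the shares were 66% and 82%, 66% and 79%, 51% and 74%, 59% and 82%, and 64% and 79%, in that order. False calls made up 0 to 0.971% of calls without the block and 7.74 to 12.1% with it, above the nominal 5%. A list that had been shifted was recovered in all 5 comparisons, and 0 of 20 unchanged lists were called. The counts were simulated from the blocked fit, with its replicate effect and dispersions, so better recovery with the block is built in. Genes were drawn independently, so the simulation does not test list calls where members are correlated.

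Gene lists for cytokine signalling, lineages, other cell types, growth and stress were tested with camera from limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the 19 lists that had at least 3 tested members. As companions, the correlation was estimated from the data and fry was run. Members were also counted past the threshold over all genes and adjusted over the list alone. No camera call for these 19 lists held with an estimated correlation, with or without the block. In that form camera tests on the residual degrees of freedom, 4 without and 3 with the block, so its power is low. The simulation did not run it. A call lost in this way does not show that a list is unchanged. T-lineage identity between gates in control cells lost its call too. Without the block fry called 0 lists in every comparison, with lowest adjusted p-values between 0.0725 and 0.830. With the block its directional test called 1, 1, 0, 0 and 4 lists in the order above. Its test for change in either direction called 11, 16, 0, 14 and 16 of the 19 lists with the block, in that order.

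Named genes were chosen by rule. For each sgStat5 effect these were the 10 highest and 10 lowest log2 fold changes among genes that passed, with mean log2 CPM of at least 2 and both sgStat5 libraries on the same side of both control libraries. For stage differences 8 per direction were taken, and for the difference between effects 5. Up to 4 members per list with the smallest adjusted p were added, along with 11 preset genes that include both targets. Predicted-gene, microRNA, snoRNA and pseudogene symbols were counted and not named. The same rule was applied to the blocked fit after the data had been seen.

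Alternatives were RLE and upper-quartile factors, DESeq2 1.42.0, limma-voom, no count filter, a filter of CPM of at least 5 in 2 libraries, a minimum fold of 2, and only the libraries of a comparison. Further ones were limma-trend on log2 FPKM with pseudocounts of 1 and 0.1 after a filter of FPKM of at least 1 in 2 libraries, and leaving out each library in turn. List medians on FPKM values use a pseudocount of 1 and only the members that pass this filter. They can therefore differ from the edgeR medians through their members and low values as well as through scaling. When 1 library is left out, its group has 1 library, which is assumed to vary like the other groups. The blocked fit under each alternative, and without genes on X and Y, was added after the data had been seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. A group of 4 further lists, for MHC class I, MHC class II, interferon-inducible GTPases and NF-kappaB, was added after the data had been seen. Their p-values were adjusted together with those of the lists fixed before. The adjusted p-values given for the fixed lists do not include the added ones. The list for the T-cell receptor gamma and delta loci was not tested, since 1 of its 18 members was in the count table. Some genes that the rule names are not reported here.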

Results

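Gene expression was measured by bulk RNA sequencing in mouse T-cell progenitors sorted on either side of T-lineage commitment, with or without CRISPR guides against both STAT5 genes. STAT5A and STAT5B are transcription factors activated by IL-7 and related cytokines. Bone-marrow progenitors from mice that carry Cas9, Bcl2 and a Bcl11b-mCherry reporter received control guides or Stat5 guides (sgStat5) and were cultured for 6 days. Bcl11b is switched on as progenitors commit to the T lineage. All sorted cells were CD25-positive, and the labels call the mCherry-negative cells pre-commitment (here the early gate) and the mCherry-positive cells post-commitment (the late gate). The series text gives the late cells as mCherry-positive yet also as reporter negative. Bcl11b RNA was higher in the late library in all 4 pairs of the same guide and replicate number, with 132 against 542, 45.6 against 219, 132 against 797 and 70.1 against 415 CPM (counts scaled to library size). Each of the 4 groups held 2 libraries. Total counts for replicates 1 and 2 were 25864734 and 31084744 in early control, 22146490 and 26989802 in early sgStat5, 26627248 and 31209177 in late control, and 22458690 and 27169689 in late sgStat5 libraries. Values below are CPM as mean ± SD with n = 2, or log2 fold changes from edgeR with a standard error (SE) derived from its F statistic. Blocked values come from the same test with the replicate number as a block.

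Both targeted genes were measured first, to set the guide labels against the RNA. Stat5a (chromosome 11, 100859351 to 100885169, mm10) stood at 257 ± 0.743 CPM in early control and 105 ± 0.648 CPM in early sgStat5 libraries, and at 248 ± 13.4 and 112 ± 5.81 CPM in the late gate. It fell by 1.29 on the log2 scale before commitment (SE 0.08, adjusted p = 0.0112) and fell by 1.15 after it (SE 0.08, adjusted p = 0.00451). Stat5b (chromosome 11, 100780731 to 100850585) stood at 252 ± 4.91 and 139 ± 7.98 CPM in the early gate and at 267 ± 17.5 and 145 ± 13.5 CPM in the late gate. It fell by 0.86 before commitment (SE 0.10, adjusted p = 0.0280) and fell by 0.89 after it (SE 0.10, adjusted p = 0.00876). In each gate both sgStat5 libraries lay below both control libraries for both genes. Neither gene passed between gates, with log2 differences of -0.05 and 0.09 in control cells for Stat5a and Stat5b. The genes are neighbours and close paralogs, so reads that match both can be counted at either, and insertions or deletions made by Cas9 need not lower the RNA.

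**Figure D1:**
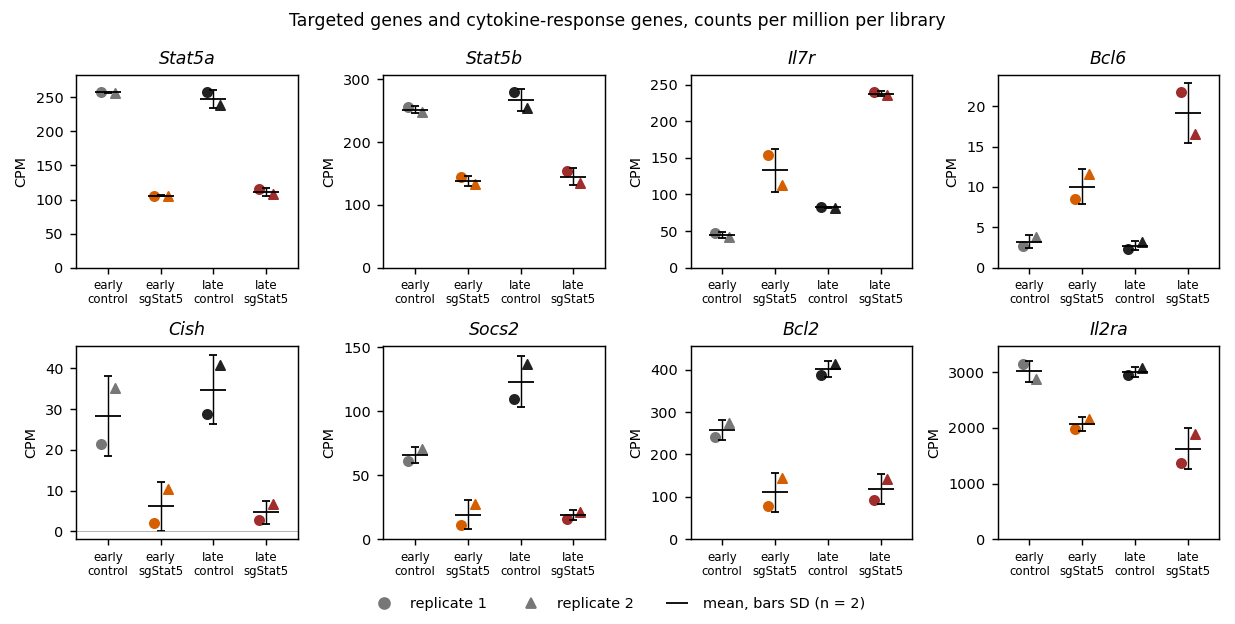
CPM per library of 8 genes (y axis, CPM, linear) in the 4 groups (x axis), with circles for replicate 1, triangles for replicate 2, lines for the mean and bars for the SD (n = 2). In both gates Stat5a, Stat5b, Cish, Socs2, Bcl2 and Il2ra lay lower in both sgStat5 libraries than in both control libraries, and Il7r and Bcl6 lay higher.

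The first comparison asks which genes depend on STAT5 before commitment. Among the largest increases, Ly6a, which encodes the stem-cell antigen Sca-1 and is also induced by interferon, went from 13.7 ± 2.22 to 77.2 ± 13.1 CPM (log2 fold change 2.49, SE 0.18, adjusted p = 0.0116). Il7r, which encodes the IL-7 receptor alpha chain, went from 44.5 ± 4.10 to 133 ± 29.3 CPM (1.58, SE 0.15, adjusted p = 0.0163). The interferon-inducible GTPases Tgtp2 (1.65, SE 0.15), Tgtp1 (1.62, SE 0.15), Gvin1 (1.60), Gbp5 (1.24), Irgm1 (1.21) and Ifi47 (0.79) rose, as did Nlrc5, an activator of MHC class I genes (1.38, SE 0.15, adjusted p = 0.0213), and Naip5 (1.41). Among the largest decreases, Rasgrp3, a Ras exchange factor, fell by 4.34 (SE 0.57, adjusted p = 0.0427), Lta, which encodes lymphotoxin alpha, fell by 3.26 (SE 0.41, adjusted p = 0.0382), and Tnfrsf9, which encodes the receptor 4-1BB, fell by 2.77 (SE 0.23, adjusted p = 0.0133). Timp3 (-2.40), Lama5 (-1.93), Tmtc2 (-1.89), Tnfsf11, which encodes RANKL (-1.79), Bhlhe40 (-1.77), Fam20a (-1.67) and Ccr4 (-1.62) also fell. Tgtp1 and Tgtp2, Gvin1 and Naip5 have close paralogs, with which reads can be shared.

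The list of STAT5-associated cytokine-response genes was lower as a group before commitment, with a median log2 fold change of -0.37 (camera adjusted p = 2.01e-05). This call was lost with an estimated correlation (adjusted p = 0.340). None of its 20 members passed over all genes, while adjusted over the list alone 2 rose and 8 fell, and with the block over all genes also 2 rose and 8 fell. In the blocked fit Cish, a STAT5-induced inhibitor of cytokine signalling, fell by 2.37 (SE 0.36, adjusted p = 0.0113; 0.594 without the block), and Socs2 fell by 1.85 (SE 0.22, adjusted p = 0.00302; 0.217). The survival gene Bcl2 fell by 1.26 (SE 0.17, adjusted p = 0.00492; 0.286), and Il2ra, which encodes the sort marker CD25, fell by 0.55 (SE 0.11, adjusted p = 0.0362; 0.339). Socs1 (-0.89), Bcl2l1 (-0.94), Il4ra (-1.47) and Lif (-0.62) fell too. The members that rose with the block were Bcl6, a repressor (1.64, SE 0.27, adjusted p = 0.0167; 0.143), and Socs3 (0.95, SE 0.20, adjusted p = 0.0471; 0.600). The mice carry a Bcl2 transgene, and whether its RNA enters the Bcl2 count is not given in the sources used here.

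Interferon-response genes were higher before commitment, with a median of 1.21 over 22 members (camera adjusted p = 1.51e-28; adjusted p = 0.340 with an estimated correlation). The medians were 1.02 and 1.48 in the replicate 1 and replicate 2 pairs, and the median on FPKM values was 0.75. Over all genes 1 member rose, Irf1 (0.69, SE 0.08, adjusted p = 0.0308), adjusted over the list alone 12 rose, and with the block 14 rose and 0 fell, with 887 genes at an unadjusted p under 0.05 in this comparison. Blocked increases were 2.55 for the nucleic-acid sensor Zbp1 (SE 0.28, adjusted p = 0.00211; 0.149 without the block) and 2.35 for Gbp2 (SE 0.21, adjusted p = 0.000816; 0.0879). The largest blocked increase that the rule named was that of Iigp1, another interferon-inducible GTPase, at 4.50 (SE 0.37, adjusted p = 0.000546; 0.162), and among the largest decreases Ndrg2 fell by 4.47 (SE 0.38, adjusted p = 0.000553; 0.143).

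Of 21 IL-7 and cytokine-receptor genes, 1 rose (Il7r) and 2 fell (the targets). Adjusted over the list alone, and with the block, 5 rose and 4 fell, and the list median of 0.07 did not pass (adjusted p = 0.465). With the block the IL-2 receptor beta chain Il2rb fell by 1.73 (SE 0.27) and the kinase Jak3 rose by 0.72 (SE 0.10). Progenitor and stem genes had a median of 0.49 (camera adjusted p = 3.33e-08; adjusted p = 0.694 with an estimated correlation). Ly6a alone of 22 rose over all genes, adjusted over the list alone 2 rose, and with the block Hoxa7 (1.43, SE 0.29) and Mef2c rose too. Genes of FOXO1-KLF2 and lymphocyte quiescence had a median of 0.14, or 0.072 on FPKM values (adjusted p = 0.00484; adjusted p = 0.708 with an estimated correlation), with Il7r the 1 member of 20 that rose by any of these counts. Ribosome-biogenesis genes had a median of -0.19 (adjusted p = 0.00128; adjusted p = 0.858 with an estimated correlation), with 0 of 22 past the threshold by edgeR with or without the block.

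T-lineage identity genes had a median of -0.12 over 26 members (adjusted p = 0.508). Over all genes 0 passed, adjusted over the list alone 1 fell, and with the block Lef1 (-1.99, SE 0.30, adjusted p = 0.0111; 0.704 without the block), Thy1 (-0.99, SE 0.08, adjusted p = 0.000553; 0.171) and Lat (-0.54) fell and Cd27 rose (0.36). Values for Bcl11b (0.19, SE 0.63), Tcf7 (0.13, SE 0.09), Gata3 (0.14, SE 0.09) and Spi1, which encodes the myeloid factor PU.1 (0.36, SE 0.45), did not pass with or without the block. Notch-response genes had a median of 0.14 (adjusted p = 0.733, with 1 of 17, Il2ra, lower in the blocked fit). Markers of other cell types did not pass: myeloid and dendritic cells (median 0.36, adjusted p = 0.199), B cells (0.43, adjusted p = 0.277), NK and innate lymphoid cells (0.05, mean and test on the lower side, adjusted p = 0.582) and mast, basophil and megakaryocyte-erythroid cells (-0.05, adjusted p = 0.590). Stromal markers, which the OP9-DLL1 cells could contribute, had a median of -0.32 (adjusted p = 0.0552; 0.0135 with the block and 0.0264 with the filter of CPM of at least 5), and Timp3 was the 1 of 18 that fell. The remaining lists did not pass: DNA replication and mitosis (0.0045, mean and test lower, adjusted p = 0.902), p53 response (-0.09, adjusted p = 0.508), BCL2 family (0.03, mean and test lower, adjusted p = 0.465), cholesterol synthesis (-0.09, adjusted p = 0.246) and immediate-early and stress response (-0.11, adjusted p = 0.733). Glycolysis had a median of -0.16 (adjusted p = 0.0552; 0.0235 with the block and 0.0264 with that filter, where in the blocked fit the enolase Eno1 fell by 0.74). Median signs of the NK, mast-cell and BCL2 lists turn with FPKM values.

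Over all 13775 genes edgeR called 37 before commitment, 17 higher and 20 lower, and with the block 321, 138 higher and 183 lower. All 37 were among the 321, with no difference in sign, and the 321 had the same sign in both replicate pairs. The unblocked count went to 1 without early control replicate 1, 0 without early control replicate 2, 16 without early sgStat5 replicate 1 and 1 without early sgStat5 replicate 2. Each of the 23 called genes named by the rule lost its call without at least 1 library. The blocked count went to 104, 170 and 196 without the first 3 of these libraries, in that order. The list calls of this comparison held without each library, and 7 lists that had not passed did so without 1. Without control replicate 2 these were cholesterol synthesis (adjusted p = 0.0289), glycolysis (0.0267) and T-lineage identity (0.00512). Others were p53 response (0.0235) without control replicate 1 and IL-7 signalling (0.0172) without sgStat5 replicate 2. Myeloid markers passed without either of a pair of libraries (0.0214 without control replicate 2 and 0.0300 without sgStat5 replicate 1), as did stromal markers (0.000123 without control replicate 1 and 3.37e-12 without sgStat5 replicate 2). The stromal median was then -1.27 and -7.16, the myeloid median 0.46 and 0.11, and those of T-lineage identity, p53 response and IL-7 signalling -0.27, -0.18 and 0.13. The stromal value of -7.16 rests on early sgStat5 replicate 1 as the only library of its group. A median this large can come from counts near 0, where a fold is not bounded.

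The next comparison asks which genes depend on STAT5 after commitment. Bcl6 went from 2.73 ± 0.561 to 19.1 ± 3.69 CPM (log2 fold change 2.80, SE 0.32, adjusted p = 0.00904) and Ly6a from 39.5 ± 3.38 to 236 ± 24.96 CPM (2.58, SE 0.17, adjusted p = 0.00451). Il7r went from 82.2 to 238 CPM (1.53, SE 0.15, adjusted p = 0.00596). The largest increase that the rule named was that of Dscam, a cell-adhesion molecule (5.07, SE 0.45, adjusted p = 0.00451). Mpeg1, which encodes perforin-2 (4.26, SE 0.69), Zbp1 (2.81, SE 0.46), Gbp2 (2.55), Rap1gap2 (2.52), Trib2 (2.47), Bcl3, a nuclear partner of NF-kappaB (2.39), and the MHC class II gene H2-Ab1 (2.28, SE 0.39) also rose. Socs2 went from 123 ± 19.7 to 18.7 ± 3.96 CPM (-2.72, SE 0.40, adjusted p = 0.0245) and Bcl2 from 400 ± 18.9 to 118 ± 34.8 CPM (-1.76, SE 0.30, adjusted p = 0.0400). Further large decreases were those of Nhsl2 (-4.16, SE 0.48), Timp3 (-3.52, SE 0.31), the imprinted RNA H19 (-3.42), Podxl (-3.28), Lilr4b (-3.26), Lilrb4a (-3.24), Lta (-3.09) and Actr3b (-2.75). Lilr4b and Lilrb4a are paralogs, with which reads can be shared.

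STAT5-associated cytokine-response genes had a median of -0.63 after commitment (camera adjusted p = 3.57e-05; adjusted p = 0.351 with an estimated correlation). Over all genes 4 of 20 fell (Socs2, Bcl2, Il2ra and Pim1) and 1 rose (Bcl6). Adjusted over the list alone 11 fell and 3 rose, and with the block 11 fell and 2 rose. Il2ra fell by 0.89 (SE 0.14, adjusted p = 0.0352) and the kinase gene Pim1 fell by 0.57. Cish went from 34.8 ± 8.45 to 4.74 ± 2.83 CPM, which passed with the block (-3.00, SE 0.37, adjusted p = 0.00148) and not without it (-2.86, SE 0.75, adjusted p = 0.161). Bcl2l1 (-1.12), Il4ra (-1.88), Ccnd2 (-0.75), Osm (-0.87) and Dusp5 (-0.69) fell and Socs3 rose (1.30) in the blocked fit.

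Interferon-response genes had a median of 1.34 after commitment (camera adjusted p = 1.10e-27; adjusted p = 0.351 with an estimated correlation), with pair medians of 1.07 and 1.91. Over all genes 5 of 22 rose, adjusted over the list alone 13 rose, and with the block 18 rose and 0 fell. Irf1 (1.22, SE 0.08, adjusted p = 0.00451) and Usp18 (1.91, SE 0.34, adjusted p = 0.0441) were among them, along with Zbp1 and Gbp2. Myeloid and dendritic markers had a median of 0.58 (adjusted p = 0.00804; adjusted p = 0.566 with an estimated correlation). Of 23, 1 rose, the interferon-regulated factor Irf8 (from 8.08 ± 1.08 to 22.8 ± 2.18 CPM, adjusted p = 0.0329), and 1 fell, the cytokine receptor chain Csf2rb (-1.87, SE 0.31, adjusted p = 0.0371). Adjusted over the list alone, and with the block, 4 rose and 1 fell, and in the blocked fit these included the MHC class II genes H2-Aa (4.61, SE 0.52, adjusted p = 0.000807; 0.208 without the block) and Cd74 (3.98, SE 0.33, adjusted p = 0.000202; 0.0943).

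T-lineage identity genes had a median of 0.22 (camera adjusted p = 0.00677; adjusted p = 0.653 with an estimated correlation), with 0 of 26 past the threshold over all genes or adjusted over the list alone, at 1713 genes with an unadjusted p under 0.05. In the blocked fit 9 rose and 1 fell. Bcl11b rose by 0.74 (SE 0.14, adjusted p = 0.0106; 0.755 without the block) and the recombinase gene Rag1 by 1.04 (SE 0.17, adjusted p = 0.00609; 0.401). The pre-T-cell receptor gene Ptcra rose by 2.97 (SE 0.53, adjusted p = 0.00923; 0.339), Tcf7 by 0.39 (0.00372; 0.109) and Gata3 by 0.36 (0.0357; 0.141), while Thy1 fell by 0.49. Spi1 did not pass with or without the block (0.59, SE 0.46). Of 17 Notch-response genes 1 fell over all genes (Il2ra), 3 rose and 3 fell adjusted over the list alone, and 5 rose and 3 fell with the block, among them Hes1 (0.58) and Cdkn1a (-1.07); the list median of 0.39 did not pass (adjusted p = 0.367). Progenitor and stem genes had a median of 0.26 (adjusted p = 0.00620; adjusted p = 0.566 with an estimated correlation), with Ly6a the 1 of 22 that rose over all genes, 2 higher and 1 lower adjusted over the list alone, and 2 higher and 2 lower with the block. Of 21 IL-7 and cytokine-receptor genes 4 rose (among them Il7r and Jak3) and 2 fell (the targets), with 8 higher and 4 lower adjusted over the list alone or with the block (median 0.23, adjusted p = 0.0237; adjusted p = 0.566 with an estimated correlation). Quiescence genes had a median of 0.23 (adjusted p = 0.00128; adjusted p = 0.502 with an estimated correlation), with 1 of 20, Il7r, higher, and 5 with the block, among them Foxo1 (0.85) and Btg1 (1.11).

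Growth-related lists were lower after commitment. Ribosome-biogenesis genes had a median of -0.30 (adjusted p = 4.95e-07; adjusted p = 0.502 with an estimated correlation), with 0 of 22 past the threshold over all genes and 9 lower with the block, among them Srm (-0.73) and Ncl (-0.43). Cholesterol-synthesis genes had a median of -0.34 (adjusted p = 2.48e-05; adjusted p = 0.502 with an estimated correlation), with 0 of 20, and 5 lower with the block, among them Lss (-0.51) and Idi1 (-0.39). Glycolysis genes had a median of -0.38 (adjusted p = 0.00121; adjusted p = 0.447 with an estimated correlation), with Eno1 lower over all genes (-1.03, SE 0.15, adjusted p = 0.0217) and 1 higher and 5 lower with the block. Lists that did not pass were DNA replication and mitosis (-0.15, adjusted p = 0.0641; 0.0330 with the block) and p53 response (-0.08, mean on the higher side, adjusted p = 0.901). The BCL2 family did not pass either (0.10, adjusted p = 0.968, with Bcl2 lower over all genes and Bcl2l1 too adjusted over the list alone). The same holds for NK and innate lymphoid genes (0.06, adjusted p = 0.270, with the integrin Itga4 higher over all genes by 0.90, and 4 higher and 2 lower with the block). Further lists were B-cell markers (0.21, adjusted p = 0.367), mast-cell and megakaryocyte-erythroid markers (0.36, adjusted p = 0.443), stromal markers (-0.06, or 0.18 with the block, adjusted p = 0.443, with Timp3 lower) and immediate-early genes (-0.05, mean and test on the higher side, adjusted p = 0.367). Median signs of the NK and stromal lists turn with FPKM values.

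**Figure D2:**
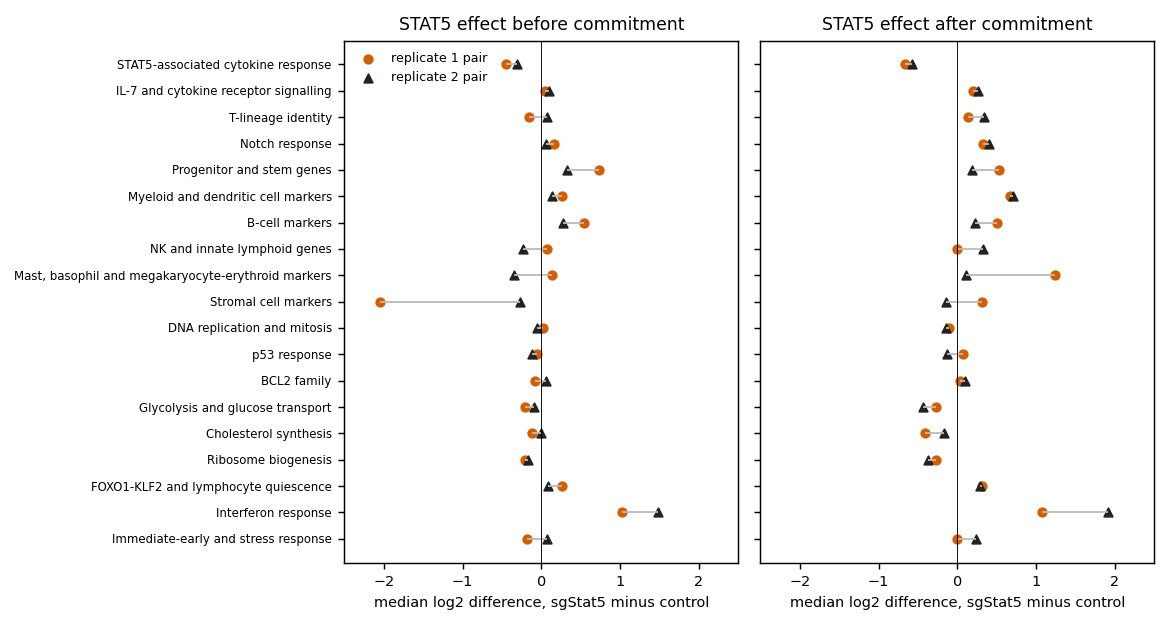
Median log2 difference between sgStat5 and control libraries (x axis) for the members of each of 19 gene lists (y axis), before (left) and after commitment (right), with 1 point per replicate pair. Interferon-response medians lay at 1.02 and 1.48 before and at 1.07 and 1.91 after commitment, above 0 in all 4 pairs.

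Over all genes edgeR called 235 after commitment, 104 higher and 131 lower, and with the block 1132, 513 higher and 619 lower. All 235 were among the 1132, with no difference in sign, and the 1132 had the same sign in both replicate pairs. On log2 FPKM with a pseudocount of 1 the higher and lower counts were 117 and 93, and with the block 504 and 352. The unblocked count went to 99 without late control replicate 1, 100 without late control replicate 2, 63 without late sgStat5 replicate 1 and 100 without late sgStat5 replicate 2, and the blocked count to 674, 524, 401 and 605. List calls ended without late control replicate 2 or late sgStat5 replicate 1 for T-lineage identity (adjusted p = 0.835 and 0.647), IL-7 signalling (0.556 and 0.0949) and quiescence (0.103 and 0.0573). They ended without late control replicate 1 or late sgStat5 replicate 2 for myeloid markers (0.587 and 0.632) and progenitor genes (0.735 and 0.973). Lists that had not passed with all libraries, and did so without 1 library, were immediate-early genes (0.00954) without sgStat5 replicate 1, NK genes without control replicate 2 (0.00989) or sgStat5 replicate 1 (0.00845), mast-cell markers (0.00989) without control replicate 2 and Notch response (0.0240) without control replicate 1. The medians were then 0.35 for immediate-early genes, 0.38 and 0.49 for NK genes and 0.96 for mast-cell markers.

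Whether the same genes respond in both gates was asked by setting the effects side by side, in comparisons that share no library. The 2 gates may still come from the same cultures, so a difference between control and sgStat5 cultures could enter both effects. Both effects also come from the same fit and share each gene's dispersion. Genes that are easy to call in 1 gate are therefore easy to call in the other. The counts expected of independent lists are thus not a chance level. The shared dispersion does not set the direction of a call. All 17 genes called higher before commitment were called higher after it, against 0.128 expected of independent lists, and 19 of the 20 called lower were called lower, against 0.190. With the block 128 of 138 higher genes and 160 of 183 lower genes were shared, against 5.14 and 8.22 expected, and 0 genes were called in opposite directions. Of the 1132 genes of the blocked fit after commitment, 1082 had the same sign before it. Across all 13775 genes, which are not independent replicates, Pearson's r was 0.34 and Spearman's rho 0.43. Within the replicate 1 and replicate 2 pairs r was 0.252 and 0.390. With a filter of CPM of at least 5 in 2 libraries r was 0.726.

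**Figure D3:**
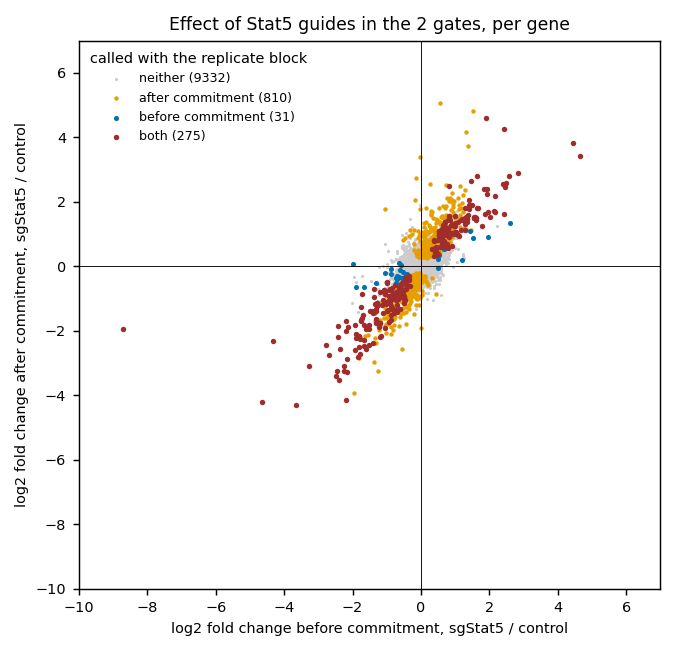
Log2 fold change between sgStat5 and control cells before (x axis) and after commitment (y axis) for 10448 genes with mean log2 CPM of at least 2, coloured by the blocked calls. The 275 genes called in both gates lie in the lower left and upper right, and 810 were called after commitment and 31 before it alone; the point farthest left is a gene with no counts in early sgStat5 libraries, whose fold is not bounded.

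Whether the effect of the guides differs between gates was tested by the interaction term. Dscam and Etv5 were the genes that unblocked DESeq2 called, and both were named after their values were seen. Dscam had a log2 fold change of 0.56 (SE 0.37) before and 5.07 (SE 0.45) after commitment, a difference of 4.54 by DESeq2 (SE 0.70, adjusted p = 1.85e-06). Etv5, an ETS-family factor, differed by 1.29 (SE 0.28, adjusted p = 0.0233) by DESeq2, with 0.08 before and 1.36 after commitment. By edgeR neither passed (adjusted p = 1 for both without the block, 0.112 and 0.245 with it). The differences for the targets were 0.14 (SE 0.11) for Stat5a and -0.02 (SE 0.14) for Stat5b. Those for Socs2 (-0.94, SE 0.53), Bcl2 (-0.55, SE 0.41), Cish (-0.69), Il2ra (-0.34, SE 0.20), Il7r (-0.05, SE 0.21), Bcl11b (0.48, SE 0.89), Tcf7 (0.26), Gata3 (0.22) and Spi1 (0.24) did not pass.

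EdgeR called 0 genes for this difference, with 302 at an unadjusted p under 0.05, and 0 with the block, with 814. Limma-voom also called 0, DESeq2 called 2, and DESeq2 with the block called 58, 38 higher and 20 lower. The 20 include 7 predicted genes with identical counts and a fold that is not bounded. Among the higher were Ntrk3 (2.88, SE 0.40) and the MHC class II genes Cd74 (2.60) and H2-Eb1 (3.94). Without a count filter the blocked edgeR fit called 11, and it called 6 without early sgStat5 replicate 2 and 1 without late sgStat5 replicate 2. Camera passed 6 lists, none of which passed with an estimated correlation (adjusted p = 0.607 for each). The higher ones after commitment were T-lineage identity (median difference 0.34, adjusted p = 3.02e-05), interferon response (0.22, adjusted p = 0.0103) and NK and innate lymphoid genes (0.27, adjusted p = 0.0483; 0.0577 with RLE factors). The lower ones were cholesterol synthesis (-0.17, adjusted p = 0.000120), ribosome biogenesis (-0.16, adjusted p = 0.00461) and DNA replication and mitosis (-0.14, adjusted p = 0.0402). On FPKM values the medians of interferon response, ribosome biogenesis and DNA replication were 0.37, -0.10 and -0.0902. With the block IL-7 signalling (0.0372; 0.0625 without it), myeloid markers (0.0302; 0.0625, with a blocked median of -0.0046 against a test on the higher side) and glycolysis (0.0197; 0.0567) passed as well. None of these blocked calls held by camera with an estimated correlation, where the lowest adjusted p over all lists was 0.541. With the filter of CPM of at least 5 in 2 libraries, IL-7 signalling (0.00868), myeloid markers (0.0376) and progenitor genes (0.0209) passed.

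Each of those 6 list calls ended without some libraries. T-lineage identity ended without early control replicate 1 (adjusted p = 0.0953), early sgStat5 replicate 2 (0.0558), late control replicate 2 (0.642) or late sgStat5 replicate 1 (0.199). Interferon response ended without early control replicate 1 (0.469), early sgStat5 replicate 2 (0.0627), late control replicate 2 (0.159) or late sgStat5 replicate 1 (0.276). NK genes ended without early control replicate 2 (0.397), early sgStat5 replicate 2 (0.226), late control replicate 1 (0.474) or late sgStat5 replicate 2 (0.869). Cholesterol synthesis ended without early control replicate 2 (0.0563) or late control replicate 1 (0.155). Ribosome biogenesis ended without early sgStat5 replicate 2 (0.0558), late control replicate 2 (0.946) or late sgStat5 replicate 1 (0.417). DNA replication ended without early control replicate 1 (0.589), early sgStat5 replicate 2 (0.224), late control replicate 2 (0.107), late sgStat5 replicate 1 (0.0748) or late sgStat5 replicate 2 (0.152).

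For this difference, 10 lists that had not passed with all libraries and no block did so without 1 library. Without late control replicate 1 these were IL-7 signalling (adjusted p = 0.00676), Notch response (0.0113), progenitor genes (0.000141), glycolysis (0.00350) and quiescence (0.00350). Without late control replicate 2 they were myeloid markers (1.97e-07), mast-cell markers (5.82e-05) and immediate-early genes (0.0472). Without late sgStat5 replicate 1 they were myeloid markers (0.000470) and immediate-early genes (0.000834). Without late sgStat5 replicate 2 they were IL-7 signalling (0.0417), progenitor genes (2.44e-05), glycolysis (0.0248) and quiescence (0.0296). Without early control replicate 1 they were myeloid markers (0.00172), stromal markers (0.00874) and glycolysis (0.0184), and without early control replicate 2 progenitor genes (0.0379) and immediate-early genes (0.0379). Without early sgStat5 replicate 1 they were STAT5 response (0.0139), IL-7 signalling (0.0319) and stromal markers (0.0297), and without early sgStat5 replicate 2 myeloid markers (0.0259) and stromal markers (8.36e-14). The median went from 0.0043 to 1.03 for myeloid markers and from 0.15 to 1.66 for mast-cell markers without late control replicate 2, and from -0.15 to -0.78 for progenitor genes without late sgStat5 replicate 2. For stromal markers it went from 0.22 to 7.07 without early sgStat5 replicate 2, which leaves replicate 1 alone in that group. Such a value can come from counts near 0, where a fold is not bounded. The list of p53 response did not pass, with a median of -0.06 against a mean of 0.42 and a test on the higher side (0.533).

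The gates were compared within control cells to describe what separates early from late cells without Stat5 guides. Gfra1, a receptor subunit for glial-derived growth factor, went from 13.3 ± 1.22 to 56.5 ± 7.82 CPM (log2 fold change 2.08, SE 0.15, adjusted p = 0.0268), and Marcks, a substrate of protein kinase C, from 204 ± 4.59 to 401 ± 18.0 CPM (0.97, SE 0.08, adjusted p = 0.0275). Bcl11b, whose reporter set the gates, went from 88.8 ± 61.1 to 380 ± 229 CPM, which passed with the block (2.14, SE 0.14, adjusted p = 0.000308) and not without it (2.10, SE 0.65, adjusted p = 0.256). In the blocked fit the T-cell receptor genes Cd3d (3.43, SE 0.35), Cd3e (2.80, SE 0.18) and Ptcra (3.64, SE 0.70) rose. The myeloid gene Mpo fell by 4.18 (SE 0.97), the integrin Itga2b by 3.20 (SE 0.63), Gfi1b by 3.12 (SE 0.79) and Tyrobp by 2.96 (SE 0.50). Spi1 fell by 1.72 (SE 0.25, adjusted p = 0.00533; 0.237 without the block), from 39.0 to 12.2 CPM. Il7r (0.89), Socs2 (0.89) and Bcl2 (0.65, SE 0.16, adjusted p = 0.0372; 0.361) rose with the block, while Cish (0.33), Il2ra (-0.01), Tcf7 (-0.12) and Gata3 (-0.22) did not pass with or without it.

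**Figure D4:**
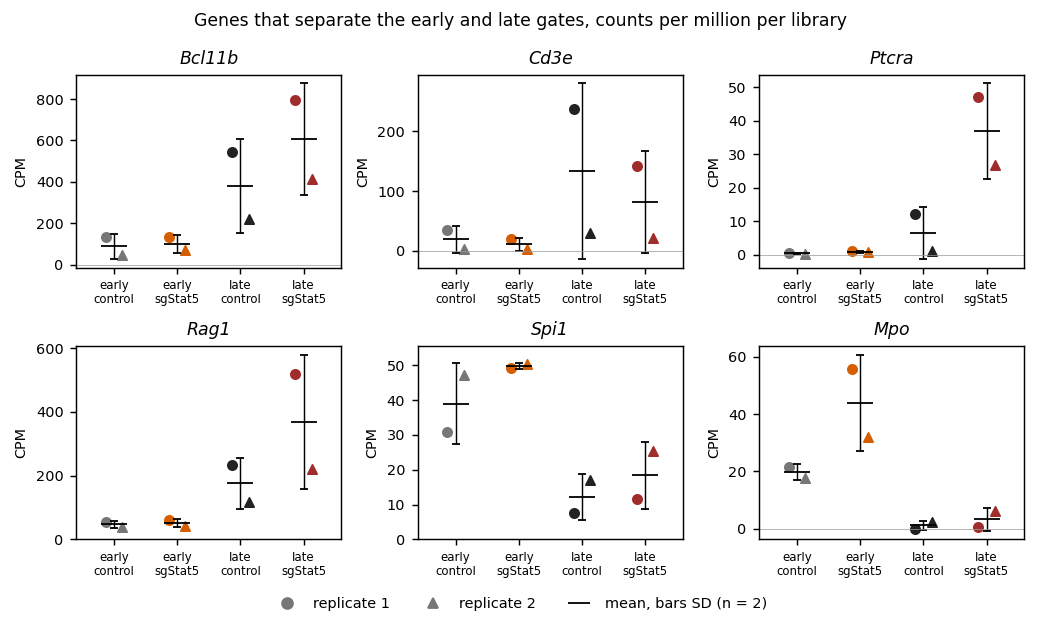
CPM per library of 6 genes (y axis, CPM, linear) in the 4 groups (x axis), with circles for replicate 1, triangles for replicate 2, lines for the mean and bars for the SD (n = 2). Bcl11b stood at 88.8 ± 61.1 CPM in early and 380 ± 229 CPM in late control cells, and replicate 1 lay above replicate 2 in every group for Bcl11b and Cd3e.

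Of 26 T-lineage identity genes 21 rose in control cells with the block, 15 adjusted over the list alone without it, and 0 over all genes (median 1.42, camera adjusted p = 1.06e-14; adjusted p = 0.327 with an estimated correlation). Quiescence genes rose as a group (0.74, adjusted p = 2.91e-09; 11 of 20 with the block, 7 adjusted over the list alone; adjusted p = 0.327 with an estimated correlation). Interferon-response genes did too (0.90, adjusted p = 7.70e-09; 11 of 22, and 6; adjusted p = 0.339 with an estimated correlation), and so did IL-7 signalling genes (0.17, adjusted p = 0.00476; 7 higher and 3 lower of 21; adjusted p = 0.339 with an estimated correlation). Ribosome-biogenesis genes were lower as a group (-0.42, adjusted p = 4.71e-13; 18 of 22, and 12 adjusted over the list alone; adjusted p = 0.327 with an estimated correlation). Progenitor genes were lower too (-0.89, adjusted p = 3.49e-05; 9 lower and 1 higher of 22; adjusted p = 0.339 with an estimated correlation), as were glycolysis genes (-0.18, adjusted p = 0.0260; 5 lower and 2 higher of 20; adjusted p = 0.339 with an estimated correlation). Of the markers of other cell types, 3 lists were lower in the late gate, with myeloid markers at -0.45 (adjusted p = 3.49e-05; adjusted p = 0.339 with an estimated correlation). NK genes stood at -0.35 (adjusted p = 5.40e-05; adjusted p = 0.327 with an estimated correlation) and mast-cell and megakaryocyte-erythroid markers at -0.85 (adjusted p = 0.00223; adjusted p = 0.327 with an estimated correlation). On FPKM values that median was -2.54, and with the block it was -1.35. The median of interferon response on FPKM values was 0.56. Stromal markers were higher with the block (median 0.86 without it, adjusted p = 0.0740; 0.00556 with it), as Thbs1 rose by 2.12, and DNA replication passed with the block too (0.19, adjusted p = 0.0740; 0.0357). Neither of these blocked calls held by camera with an estimated correlation, where the lowest adjusted p over all lists was 0.297. Lists that did not pass were STAT5 response (0.16, adjusted p = 0.268), Notch response (0.09, adjusted p = 0.501) and B cells (0.67, adjusted p = 0.856). Others were p53 response (-0.04, mean on the higher side, adjusted p = 0.856), BCL2 family (adjusted p = 0.162), cholesterol synthesis (adjusted p = 0.566) and immediate-early genes (-0.20, adjusted p = 0.0694).

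Over all genes edgeR called 2 in control cells, Gfra1 and Marcks, with 2049 at an unadjusted p under 0.05, and 1507 with the block, 914 higher and 593 lower. The unblocked count went to 0 without early control replicate 1, early control replicate 2 or late control replicate 1, and to 32 without late control replicate 2. The blocked count went to 161 without early control replicate 1 and 169 without late control replicate 1. The glycolysis call ended without early control replicate 1 (adjusted p = 0.172) or late control replicate 1 (0.106). Lists that had not passed with all libraries and no block, and did so without 1 library, were DNA replication (0.000181), immediate-early genes (0.00884) and stromal markers (0.00110) without early control replicate 2. The others were DNA replication (0.0189), immediate-early genes (0.0300), stromal markers (0.00110) and STAT5 response (0.0439) without late control replicate 1, and Notch response (0.0351) without late control replicate 2. The stromal median was then 3.01 without early control replicate 2 and 1.54 without late control replicate 1, that of immediate-early genes -0.47 and -0.29, and that of Notch response -0.0174 with its test on the higher side.

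The gates were compared in the same way within sgStat5 cells. The chemokine receptor gene Ccr9, which is known in thymus homing, had the largest increase among named genes that passed without the block (6.62, SE 1.06, adjusted p = 0.0486), from 0.145 to 14.5 CPM. Ntrk3 (4.06, SE 0.54), Rasgrp3 (3.85), Serinc5 (2.92), Wfs1 (2.91), Gfra1 (2.47, SE 0.15, adjusted p = 0.00842), Nsg2 (2.41) and the integrin Itgae (2.29) rose. Trpm2 (-2.81, SE 0.33), the dendritic-cell integrin Itgax (-2.66, SE 0.41), Kcnk12 (-2.60), March1 (-2.56), Dok3 (-2.32), Mef2c, a factor of lymphoid and myeloid progenitors (-2.29, SE 0.29, adjusted p = 0.0480), Card9 (-2.18) and Afap1l1 (-2.14) fell. Bcl11b passed with the block (2.58, SE 0.14, adjusted p = 3.76e-05; 0.0908 without it), as did Spi1 (-1.55, SE 0.25, adjusted p = 0.00347; 0.131), Il7r (0.85; 0.00136 and 0.0572) and Il2ra (-0.35, adjusted p = 0.0475). Socs2 (-0.04, SE 0.38), Bcl2 (0.09, SE 0.29), Cish (-0.39, SE 0.73), Tcf7 (0.15), Gata3 (0.00), Stat5a (0.08) and Stat5b (0.06) did not pass with or without the block.

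In sgStat5 cells 4 of 26 T-lineage genes rose over all genes (among them Thy1 by 1.43 and Ets2 by 1.68), 19 adjusted over the list alone and 23 with the block (median 1.67, camera adjusted p = 1.09e-19; adjusted p = 0.355 with an estimated correlation). Also higher as groups were quiescence genes (0.79, adjusted p = 2.42e-08; Foxo1 and Bach2 over all genes, 12 adjusted over the list alone; adjusted p = 0.355 with an estimated correlation). Interferon-response genes were higher as well (1.02, adjusted p = 2.29e-11; Irf1 over all genes, 11 adjusted over the list alone, 18 with the block; adjusted p = 0.355 with an estimated correlation), and so were IL-7 signalling genes (0.42, or 0.24 with the block, adjusted p = 0.000272; Ifngr1 and Il6st over all genes; adjusted p = 0.355 with an estimated correlation). Ribosome-biogenesis genes were lower (-0.57, adjusted p = 1.83e-15; Utp20 over all genes, 21 of 22 adjusted over the list alone; adjusted p = 0.355 with an estimated correlation). Progenitor genes were lower too (-1.08, adjusted p = 7.27e-06; 1 higher and 11 lower adjusted over the list alone; adjusted p = 0.488 with an estimated correlation), as were glycolysis genes (-0.32, adjusted p = 0.00156; 1 higher and 5 lower; adjusted p = 0.355 with an estimated correlation). Stromal markers passed with the block (median 1.23 without it, adjusted p = 0.0513; 2.11 with it, adjusted p = 0.00220), with pair medians of 4.78 in replicate 1 and 0.85 in replicate 2. The blocked stromal call did not hold by camera with an estimated correlation, where the lowest adjusted p over all lists was 0.224. The other lists did not pass, among them myeloid markers (adjusted p = 0.0539), NK genes (0.110) and cholesterol synthesis (0.0513). With the filter of CPM of at least 5 in 2 libraries, the mast-cell and megakaryocyte-erythroid list (median -2.30 against -1.22, adjusted p = 0.0110; 0.195 with the default filter) and stromal markers (0.0402) passed. Median, mean and test differed in sign for STAT5 response (-0.10, mean and test higher), DNA replication (0.04, test lower), BCL2 family (0.06, test lower) and immediate-early genes (0.05, mean and test lower).

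Over all genes edgeR called 134 in sgStat5 cells, 91 higher and 43 lower, and with the block 3144, 1562 higher and 1582 lower. On log2 FPKM with a pseudocount of 0.1 the counts were 88 higher and 23 lower. The unblocked count was 0 without any 1 of the 4 sgStat5 libraries, and the blocked count went to 1119 without early sgStat5 replicate 1, 886 without late sgStat5 replicate 1 and 2065 without late sgStat5 replicate 2. Lists that had not passed with all libraries and no block, and did so without 1 library, were cholesterol synthesis (adjusted p = 0.0167) and stromal markers (0.00153) without late replicate 1. Myeloid markers passed without early replicate 1 (0.0162) or late replicate 2 (0.00949), NK genes without early replicate 2 (0.0473) or late replicate 2 (0.0267), and stromal markers (2.16e-09) without early replicate 2. The stromal median was then 7.89, the myeloid median without late replicate 2 -1.48, and the NK median without early replicate 2 -0.26. That stromal value rests on early sgStat5 replicate 1 alone in its group and can come from counts near 0, where a fold is not bounded. In the blocked fits 732 genes were higher and 510 lower in the late gate in both guide arms, against 104 and 68.1 expected of independent lists, and 2 were called in opposite directions. The arms share each gene's dispersion in the fit, so these expected counts are not a chance level. Across genes r between the stage differences was 0.58 and rho 0.67.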

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

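The blocked fit with DESeq2 was chosen after the data had been seen, and the other tests were fixed before. The sgStat5 effect on 6 gene lists differed between the gates by camera at its preset correlation. The median difference, late minus early, was 0.34 for T-lineage identity, 0.22 for interferon response and 0.27 for NK and innate lymphoid genes. It was -0.17 for cholesterol synthesis, -0.16 for ribosome biogenesis and -0.14 for DNA replication and mitosis. None of these calls held with an estimated correlation (adjusted p = 0.607 for each), and fry called none of them (adjusted p = 0.830 for each). The number of libraries that ended the call when left out was 4 for T-lineage identity, 4 for interferon response, 4 for NK genes, 2 for cholesterol synthesis, 3 for ribosome biogenesis and 5 for DNA replication. No single gene of these lists passed the interaction test by edgeR with or without the block. DESeq2 with the block called Thy1 (0.52, adjusted p = 0.0107) and Rag1 (0.93, 0.0150) of T-lineage identity, Irf1 (0.54, 0.00676) of interferon response and Gzma (0.64, 0.0136) of the NK genes. The cause of these differences was not tested, and they stay open.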

How the results depend on the processing

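Settings with the replicate block beyond the first blocked count, and those without X and Y genes, were chosen after the data had been seen.

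The 37 genes before commitment became 247 with DESeq2, 114 without a count filter, 3 with only the libraries of the comparison and 321 with the block, and 0 to 16 without 1 library. The blocked 321 became 525 with DESeq2, 486 with only those libraries, 203 and 207 on log2 FPKM with pseudocounts of 1 and 0.1, 162 with a fold of at least 2, and 104 to 259 without 1 library. The 235 after commitment became 609 with DESeq2, 4 with only those libraries, 1132 with the block, and 63 to 100 without 1 library. The blocked 1132 became 2273 with only those libraries, 433 with a fold of at least 2, and 401 to 674 without 1 library. For the difference between effects DESeq2 gave 2. In its blocked fit DESeq2 gave 58, the fit without a filter 11, and the fits without 1 library 0 to 6.

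In control cells the 2 genes between gates became 552 with DESeq2, 83 without a filter, 0 with only those libraries, 1507 with the block, 1 with a fold of at least 2, and 0 to 32 without 1 library. The blocked 1507 became 921 and 888 on log2 FPKM, 407 with a fold of at least 2, and 161 to 1633 without 1 library. In sgStat5 cells the 134 became 1623 with DESeq2, 75 with limma-voom, 760 without a filter, 231 with CPM of at least 5, 2 with only those libraries, 3144 with the block, 89 with a fold of at least 2, and 0 without any 1 library. The blocked 3144 became 871 with a fold of at least 2 and 886 to 2695 without 1 library. The correlation between the effects became 0.726 with CPM of at least 5.

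Fewer residual degrees of freedom follow by construction when only the libraries of a comparison are fitted. Unblocked counts fell in those fits. Blocked counts rose for the sgStat5 effects (321 to 486 before and 1132 to 2273 after commitment). They fell for the stage differences (1507 to 1014 in control and 3144 to 2560 in sgStat5 cells). The cause of the shifts was not tested. Without genes on X and Y the blocked counts were 316, 1106, 0, 1490 and 3067.

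Of list medians, that of T-lineage identity after commitment ran from -0.0714 (without late control replicate 2, where it turned) to 0.68, and that of progenitor genes from -0.22 (without late sgStat5 replicate 2) to 0.96. For the difference between effects the stromal median of 0.22 ran from -1.80 to 7.07 and turned to -0.62 without early sgStat5 replicate 1. The value of 7.07 came without early sgStat5 replicate 2 and can come from counts near 0, where a fold is not bounded. Without late control replicate 2 the ribosome median turned to 0.036, with a lowest value of -0.33, and the interferon median to -0.19, with a highest value of 0.76. Where a call ended with the test's direction kept, the median alone fell below 0 after commitment for T-lineage identity (-0.0455 without late sgStat5 replicate 1), progenitor genes (-0.21 without late control replicate 1) and myeloid markers (-0.13 without late sgStat5 replicate 2). It did so for the difference in T-lineage identity (-0.00692 without late control replicate 2) and interferon response (-0.0744 without early control replicate 1). No named gene reversed. Of the called named genes, 23 of 23, 23 of 31, 2 of 2 and 29 of 29 lost the call without some library, in the order before, after, control and sgStat5. Limma-voom lost 5, 5, 0 and 20, and the fit of only the libraries of a comparison lost 21, 30, 2 and 28. The block lost none, and changed no call other than those given in the report and the genes it added.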

Other observations

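The 4 gene lists of this part, and the test on the pairs in the interferon pattern, were chosen only after the result was seen. The p-values of these lists follow from a choice made on the same data and are no independent support. Antigen-presentation genes were higher in sgStat5 cells after commitment. Of 13 MHC class I presentation genes 7 rose, and 11 with the block, with a median of 0.60 and pair medians of 0.65 and 0.59 (camera adjusted p = 1.42e-23; adjusted p = 0.0314 with an estimated correlation, 0.0849 with the block as well). B2m rose by 0.83 (adjusted p = 0.00648), the peptide transporter Tap1 by 1.07 (0.00702) and Nlrc5 by 1.59 (0.00498). Of 10 MHC class II genes 1 rose, and 7 with the block, with a median of 1.94 (3.95e-12; adjusted p = 0.0314 with an estimated correlation, 0.0849 with the block as well). Class II genes also mark dendritic cells and other myeloid cells, whose list had a median of 0.58 after commitment (camera adjusted p = 0.00804; adjusted p = 0.566 with an estimated correlation), with 4 higher, among them Irf8, and 1 lower with the block. Of their markers Cst3 stood at 53.6 CPM in control and 52.7 CPM in sgStat5 libraries, and Tyrobp at 7.31 and 10.95 CPM. Mpo, which was near 0, stood at 0.0383 and 2.32 CPM in the late control and at 0.530 and 6.20 CPM in the late sgStat5 libraries. The class II activator Ciita rose by 3.92 in the blocked fit (SE 0.46, adjusted p = 0.00101; 0.0643 without the block). Of 16 interferon-inducible GTPases 9 rose, and 14 with the block, with a median of 1.35 (1.34e-47; adjusted p = 0.0314 with an estimated correlation, 0.0849 with the block as well).

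Before commitment 1 class I gene rose, and 6 with the block (median 0.24, camera adjusted p = 1.14e-13; adjusted p = 0.104 with an estimated correlation). None of the class II genes passed by edgeR with or without the block (median 0.83, adjusted p = 0.000700; adjusted p = 0.143 with an estimated correlation). Of the GTPases 6 rose, and 11 with the block (median 1.06, adjusted p = 1.14e-55; adjusted p = 0.0525 with an estimated correlation). These 6 are the GTPases already named among the increases before commitment, so the list p-value does not test them anew. The difference between gates was 1.13 for class II genes (adjusted p = 3.92e-09; adjusted p = 0.0718 with an estimated correlation) and 0.24 for class I genes (3.13e-07; adjusted p = 0.316 with an estimated correlation). For the GTPases it was 0.21 (0.00955; adjusted p = 0.551 with an estimated correlation). Reads of class I genes can be shared among paralogs, and 2 class II genes and 1 GTPase also stand in the lists fixed before the data were examined.

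Of 16 NF-kappaB pathway genes 2 rose after commitment, Bcl3 (2.39) and the adhesion gene Icam1 (1.08), and 3 fell, among them Nfkb1 (-0.55) and Map3k8 (-1.87). With the block 7 rose and 3 fell, and Relb rose by 2.10 (SE 0.34). The median of 0.68 passed (adjusted p = 0.0119; adjusted p = 0.514 with an estimated correlation). Before commitment the median was -0.06 (adjusted p = 0.121), with Tnfrsf9 lower (-2.77). With the block Bcl3 rose there too (1.85, adjusted p = 0.00620; 0.119 without it), and Nfkb1 (-0.58) and Map3k8 (-2.13) fell too. The difference was 0.54 (adjusted p = 2.01e-07; adjusted p = 0.380 with an estimated correlation).

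Interferon-response genes were higher in sgStat5 cells in both gates. The lowest of the 4 pair medians was 1.02 with pairs formed by replicate number. The rise was thus not carried by 1 replicate number alone. A constant difference between replicate numbers cancels within a pair by design, but a mix of cells by sex that differs between guide arms does not. Handling that set control apart from sgStat5 libraries was not tested. Medians were taken of 11 of 23 myeloid markers, with mean log2 CPM of at least 2 and without the class II genes H2-Aa and Cd74. They lay below those of the interferon genes by a gap of -1.18 (SE 0.374) in the gate with the smaller gap, and -1.23 (SE 0.207) in the other. SEs of medians in this paragraph come from a bootstrap over genes and do not measure spread between libraries. Myeloid cells carried in need not raise markers that the other cells already express as much, so they stay open as a source. With all 23 the blocked medians were 0.35 before and 0.65 after commitment, against 1.37 and 1.45 for the interferon genes. The T-lineage median before commitment was -0.12 (SE 0.177), which argues against a larger share of later cells as the whole cause there. Among the other hypotheses left open, none of which was tested, STAT5 may restrain these genes, or the cells may respond to cytokine made in the cultures. Blocking the interferon receptor in the cultures would test the second.

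Replicate 1 libraries differed from replicate 2 libraries in all 4 groups. Xist, which is expressed from the inactive X chromosome, stood at 0 to 0.360 CPM in replicate 1 and at 1370 to 2355 CPM in replicate 2, and the Y-linked gene Ddx3y at 101 to 123 CPM in replicate 1 and at 29.4 to 45.4 CPM in replicate 2. Replicate 2 thus may hold cells of both sexes. Within replicate 2, Ddx3y stood higher in sgStat5 than in control libraries, at 45.4 against 34.3 CPM early and 39.9 against 29.4 CPM late. Kdm5d, Eif2s3y and Uty went the same way. Xist stood at 1370 against 1406 CPM early and 2355 against 1999 CPM late. The mix may therefore differ between guide arms, which the block does not remove. Without X and Y genes the lowest of 6 correlations of replicate deviations between groups was 0.415, over 13303 genes. Genes on X and Y thus do not carry the difference alone. Sex can also change genes on other chromosomes and goes with the replicate number. This test therefore cannot set sex apart from other causes. Whether replicate 1 cells had moved further toward the late gate cannot be told apart from other causes: the lower correlation of the replicate difference with a stage difference from other libraries was -0.00683 and at higher expression the pair was 0.172 and 0.274.

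After commitment Bcl11b, Rag1 and Ptcra rose with the block both with sgStat5 and with stage in control cells. Other stage genes lay on the other side and did not pass: Cd3e stood at 237 and 29.7 CPM in control and at 142 and 21.8 CPM in sgStat5 libraries, and Spi1 at 7.54 and 16.9 and at 11.7 and 25.3 CPM. The lower correlation between the effect in 1 replicate pair and the stage difference in the other was -0.0142, and the other was 0.111. The late control libraries enter the effect and the stage difference with opposite signs, so sharing them cannot make a gene rise in both, and these values do not show a link across all genes. Of 500 early-gate genes the median effect was 0.13 in pair 1 (SE 0.039) and -0.09 in pair 2 (SE 0.030), where cells further along would have lower values in both. Late-gate genes were higher in both pairs (0.153, SE 0.0384, and 0.317, SE 0.0445). Only pair 1 goes against such a shift, it has 1 library per group, and the SE is taken over genes, so a shift stays open.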
